A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

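The series holds maps of 5-hydroxymethylcytosine (5hmC) in single cells of early mouse embryos and in single cells of H9, an established human embryonic stem cell line. 5hmC is the first oxidation product of 5-methylcytosine. Per the labels' protocols, 5hmC was glucosylated with T4 β-glucosyltransferase, and the DNA was digested with AbaSI, an enzyme that cleaves at a distance from glucosylated 5hmC, so that each ligated end marks 1 modified cytosine and its strand. In 3 of the 4 H9 libraries, per the labels, the DNA of the same cells was also digested with BseRI, with AluI or with both, restriction enzymes that do not depend on 5hmC and so sample genomic DNA. Embryo cells were separated with a capillary and H9 cells were sorted by flow cytometry, per the labels.

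The deposited values are in no standard unit. Each line that the authors deposited is 1 detection, given as a cell number, a chromosome, a position and a strand. Reads were aligned with BWA, for which no version was given, to mm10 for mouse and hg19 for human, per the submitters' processing notes. Duplicate removal is named in the titles of the deposited tables, and in the mouse tables no line was repeated. Repeated lines in some H9 tables were counted once here. Because duplicates were removed before deposit, a detection stands for a modified site seen in a cell and not for a number of reads. The positions were checked against the genome: all AbaSI detections on autosomes and X (100%) lay at the C of a CpG, against 0% for BseRI and 0.0260% and 0.0251% for AluI in its libraries. AluI detections carry no usable strand and were left out of strand statistics.

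A cell was a well barcode with at least 500 detections, which left 11 to 28 cells per mouse library and 30 to 58 cells with 5hmC per H9 library. A table of the authors also assigns well barcodes to 28 embryos, namely 13 embryos at the 4-cell stage with 52 cells, 14 at the 8-cell stage with 109 cells and 1 at the 16-cell stage with 16 cells. Samples were grouped by their titles and descriptions. The descriptions use the words HybEmb and NonHybEmb for different runs although the strain label is the same, so the name and the run cannot be told apart. Nothing says that plates came from separate litters or days, so p-values over plates measure only the spread between these plates, which may be technical. The 16 pairs of replicate plates of 1 group differed by more than sampling noise, with chi-square per degree of freedom from 1.42 to 6.03 over 1-Mb bins, so each plate counted as 1 replicate.

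Strand asymmetry of a cell was the mean over autosomes with at least 10 detections of the share of detection pairs on the same strand minus the share on opposite strands. It is 0 where both strands are alike and 1 where all 5hmC of each chromosome lies on 1 strand, and its expectation for a given chromosome does not depend on depth. Persistence along a chromosome was a same-strand excess for pairs 50 to 100 Mb apart divided by that for pairs 10 kb to 5 Mb apart. For this excess the pairs of a cell were summed over its autosomes, and the plate value was the mean over cells. Autosomes with more detections thus weigh more in it, so its values are not on the scale of strand asymmetry, where autosomes weigh equally. The complementary strand pattern was, for each cell, the most negative Pearson correlation of plus-strand shares over autosomes with another cell of its plate, minus the same value for as many cells drawn from other plates of its group (1000 draws). On simulated cells of known asymmetry and persistence the code was off by at most 0.0119 over 9 values. Plates were compared with two-sided exact permutation tests of group means, and the complementary pattern with an exact sign-flip permutation test. For 3 against 5 plates there are 56 splits and the smallest p is 0.0357. Benjamini-Hochberg adjusted values are given over the 3 plate measures, over the 3 measures between runs and over the 5 embryo measures computed, of which the share of the first cell and the effective number of cells depend on the number of cells of an embryo and are not compared between stages.

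Detections were summed over the cells of a plate in 1-Mb bins and in protein-coding gene bodies, from start to end on both strands, with the GENCODE annotation release M21 for mouse and release 44, mapped to the build of the files, for human. A count model had been planned for these sums. It was kept for counts as deposited, and the deposited columns hold positions, so limma-trend was used in its place. The sums made here are whole numbers to which a count model could also be fitted, which was not tried. Limma-trend was run on log2 of CPM, the detections of a region scaled to the total of its plate, with 0.5 added to each sum. The library size was the number of detections in cells on autosomes and X, and fold changes are on that scale, which understates changes of regions with few detections. A region was tested where at least as many plates as the smaller group has had 5 or more detections. The threshold was an adjusted p of 0.05. Data simulated from the plates' own means, with a dispersion of 0.03, showed what this could find: of 100 bins changed 2-fold 79.0% were called and of 100 changed 4-fold 100%, among 2560 bins. For genes it called 24.7% of 77 changed 2-fold and 84.5% of 84 changed 4-fold, among 3947 genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The 10 lists covered pluripotency, trophectoderm, primitive endoderm, zygotic genome activation, DNA methylation machinery, imprinted genes, long neuronal genes, Hox genes, cumulus and granulosa cells, and housekeeping genes. For H9 the human genes of the same symbols were used, and the median density of a list was placed among 10000 random lists. In these a member far from the others was matched on its length decile, and members whose starts lay within 1 Mb of the next were replaced together, by genes with the same steps in gene order and a median length within 2-fold.

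Groups, tests, gene lists and most alternatives were fixed before the data were examined. Genes and bins named in the text follow a rule fixed then: those past the threshold or, with fewer than 10, also the 10 with the lowest p in each direction, and for each list the members that pass or the 3 with the most detections. In H9 the rule took the 15 genes of highest density with at least 20 kb and 100 detections in the AbaSI-only library, and the 10 of lowest density, of which 3 are not reported here. Analyses by embryo, by annotation class and per CpG, gene lists included, and the joint drawing of neighbouring list members were added after the data had been seen, as were voom weights, a pseudocount of 2, median-of-ratios scaling of bins and genes, autosomes only, fry as a replacement, and rankings in other H9 libraries. The other alternatives were the minimum number of detections of a cell and of a chromosome, thinning of cells to 500 detections, other distance classes, other bin sizes, no filter, both runs together, and leaving out each plate. Promoters were the 1000 bp to either side of a transcription start, and a CpG was called CpG-dense with at least 10 CpGs within 100 bp to either side. Each class was set against its share of the CpGs of the genome. The H9 libraries are single, so they were not tested. Intervals there are exact 95% Poisson intervals, and the limit of a count of 0 is 3 counts; both cover counting error only. Shares of the X chromosome are given for mouse embryos alone. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.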

Results

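5hmC was mapped with strand in single cells of mouse embryos at the 4-, 8- and 16-cell stages and in H9 human embryonic stem cells. The mouse data comprised 3 libraries of 4-cell embryos, 5 plates of 8-cell embryos and 1 plate with 8- and 16-cell embryos from 1 run, and 3 plates of 8-cell embryos from another run, here called run 2 and run 1. Mouse libraries held from 67649 to 762936 detections. The 3 plates of run 1 were the deepest, with 526727 to 762936, and those of run 2 held at most 169351. The H9 libraries held 1025462 5hmC detections with BseRI, 321903 with BseRI and AluI, 225511 with AluI and 1320050 with AbaSI alone. The comparisons asked how much 5hmC a cell carried at each stage, whether it lay unevenly on the strands of its chromosomes, and which regions carried it.

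More 5hmC sites were detected per cell in 4-cell libraries than in 8-cell plates of the same run. Sites per cell also depend on sequencing depth, which the detections do not give, so the difference cannot be read as one of stage alone. The median per cell was 8200 ± 2608 sites in the 3 libraries of 4-cell embryos (SD) and 3926 ± 1172 in the 5 plates of 8-cell embryos. The lowest 4-cell library stood at 6251 and the highest 8-cell plate at 5491. The difference of 1.07 on the log2 scale gave the smallest p that 56 splits allow (exact permutation p = 0.0357, adjusted p = 0.107 over 3 measures), so it did not pass after adjustment. With the 8-cell plates of both runs together the difference was 0.07 (exact permutation p = 0.921, 3 against 8), because run 1 held 24085 ± 4316 sites per cell (n = 3). Between 13 embryos at the 4-cell stage and 7 at the 8-cell stage of run 2, from the authors' list, it was 0.80 (exact permutation p = 0.00111, adjusted p = 0.00292 over 5 measures). The 7 include 1 embryo of the plate with 8- and 16-cell embryos, which is outside the comparison of plates. These 13 embryos come from the same 3 libraries and share their preparation, so that p is too small and does not replace the test over plates.

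5hmC lay unevenly on the strands of single autosomes at both stages. Strand asymmetry was 0.423 ± 0.055 in 4-cell libraries (SD, n = 3) and 0.483 ± 0.061 in 8-cell plates of run 2 (n = 5), where 0 means equal strands. The difference of -0.059 was about the size of the spread between plates (exact permutation p = 0.214, adjusted p = 0.214). It was -0.152 with at least 30 detections per chromosome and -0.204 with each cell thinned to 500 detections (exact permutation p = 0.0357 for each), settings that leave out chromosomes with few detections. Persistence from short to long distances was 0.718 ± 0.042 in 4-cell libraries and 0.784 ± 0.046 in 8-cell plates of run 2, a difference of -0.066 (exact permutation p = 0.107, adjusted p = 0.161). Without 4-cell library 2 the difference in asymmetry was -0.028 and that in persistence -0.042, and without 8-cell plate 9 that in asymmetry was -0.035. Wells 25 and 28 of 4-cell library 2, in no listed embryo, had an asymmetry of 0.043 and 0.048. The listed embryos of that library stood at 0.445 and 0.432. Wells 22 and 24 of 8-cell plate 6, also unlisted, had -0.0019 and -0.00014. Some wells of listed embryos were low too, with 0.071 and 0.027 in wells 1 and 17 of 8-cell plate 1 and 0.121 in well 16 of 4-cell library 1. All these wells were counted as cells, those of listed embryos also in the embryo measures. What they hold was not tested. With the 8-cell plates of both runs the difference in persistence was -0.099 (exact permutation p = 0.0364, 3 against 8), because run 1 stood at 0.872 ± 0.024 (n = 3). Run 1 holds no 4-cell library, so this difference mixes run and stage.

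**Figure D1:**
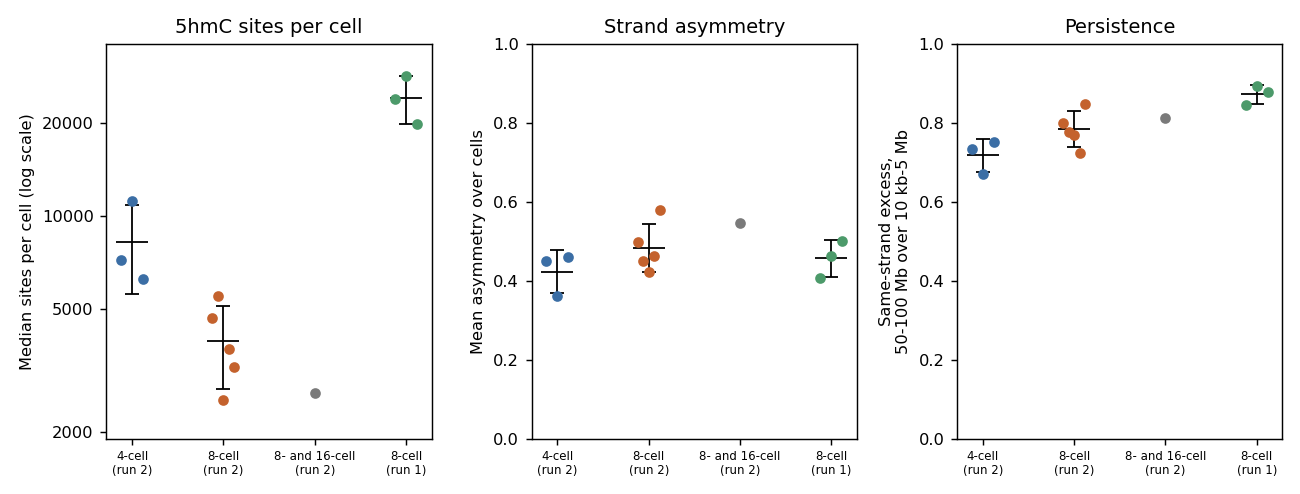
Median 5hmC sites per cell (log axis), mean strand asymmetry and persistence for each mouse plate (points), with the mean and SD of each group of 3 or 5 plates (black); the 8- and 16-cell plate is single. The 4-cell libraries lie between 6251 and 11163 sites per cell and the 8-cell plates of run 2 between 2526 and 5491, while the asymmetry of these groups overlaps.

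Pairs of detections on the same autosome were on the same strand far more often than on opposite strands, up to distances of many megabases. At 10 kb to 5 Mb the same-strand excess was 0.677, 0.532 and 0.666 in the 4-cell libraries 1, 2 and 3, and from 0.747 to 0.880 in the 8-cell plates of run 2. At 50 to 100 Mb it was 0.496, 0.357 and 0.50 in the same 4-cell libraries, and from 0.574 to 0.747 in those 8-cell plates. These values enter persistence and were not tested on their own.

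**Figure D2:**
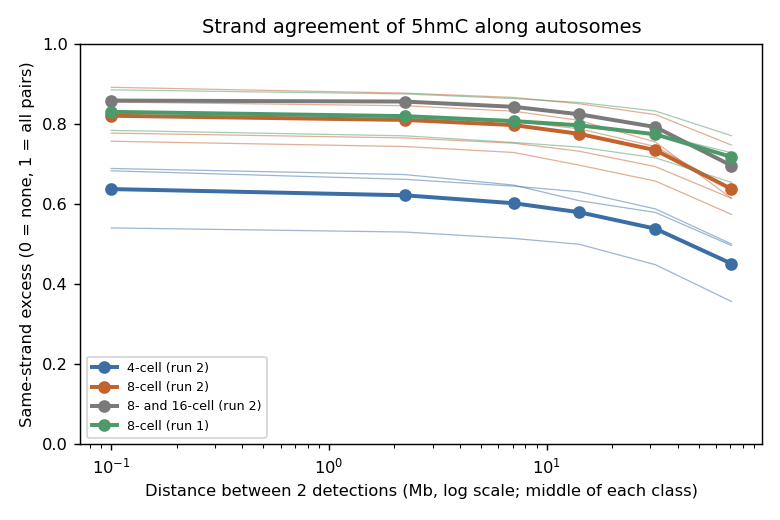
Same-strand excess of 5hmC detections (0, as many pairs on the same as on opposite strands; 1, all pairs on the same strand) against the distance between them in Mb (log axis), for each mouse plate (thin lines) and the mean of each group (thick lines with points). The 4-cell libraries lie below the other plates at each distance class, with 0.357 to 0.50 at 50 to 100 Mb.

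Cells of a plate mirrored each other's strand pattern more closely than cells of different plates. The most negative correlation of a cell's plus-strand shares with another cell was -0.586 ± 0.046 within 4-cell libraries (SD, n = 3), against -0.392 ± 0.034 with drawn partners. In 8-cell plates of run 2 it was -0.536 ± 0.037 against -0.452 ± 0.014 (n = 5), and in those of run 1 -0.517 ± 0.029 against -0.442 ± 0.023 (n = 3). The value within plates minus that of drawn partners averaged -0.111 over the 11 plates and was negative in 11 of 11 (exact sign-flip permutation p = 0.000977, the smallest this test can give).

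The 5hmC of a chromosome strand was concentrated in few cells of an embryo. For these shares each cell was first scaled to its own total over the autosomes. A share thus compares cells as if all had equal totals, and is no share of the embryo's detections. In 13 embryos at the 4-cell stage the cell with most, the first cell, held 64.1% ± 4.1 of a chromosome strand (SD over embryos), and the second cell 20.9% ± 2.0. Of these embryos 2 had only 3 cells past the minimum, and the 11 with all 4 stood at 63.7% ± 4.3. In 14 embryos at the 8-cell stage, 3 of them with 7 cells listed, the first cell held 56.6% ± 6.5 and the second 19.9% ± 2.8. Within run 2 the first cell of 7 such embryos held 53.6% ± 7.2, and within run 1 that of 7 held 59.6% ± 4.4. The 16-cell embryo, with 15 of its 16 cells past the minimum, stood at 49.6%. For comparison, each cell's detections were spread over chromosome strands by the shares of the whole embryo. This removes differences between cells in chromosomes as well as in strands. The first cell then held 28.3% ± 3.1 at the 4-cell stage (35.0% and 35.3% in the 2 embryos with 3 cells), 14.2% ± 0.9 at the 8-cell stage and 8.45% at the 16-cell stage. The share that goes with no pattern falls with the number of cells, so the first cell's share was not compared between stages.

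**Figure D3:**
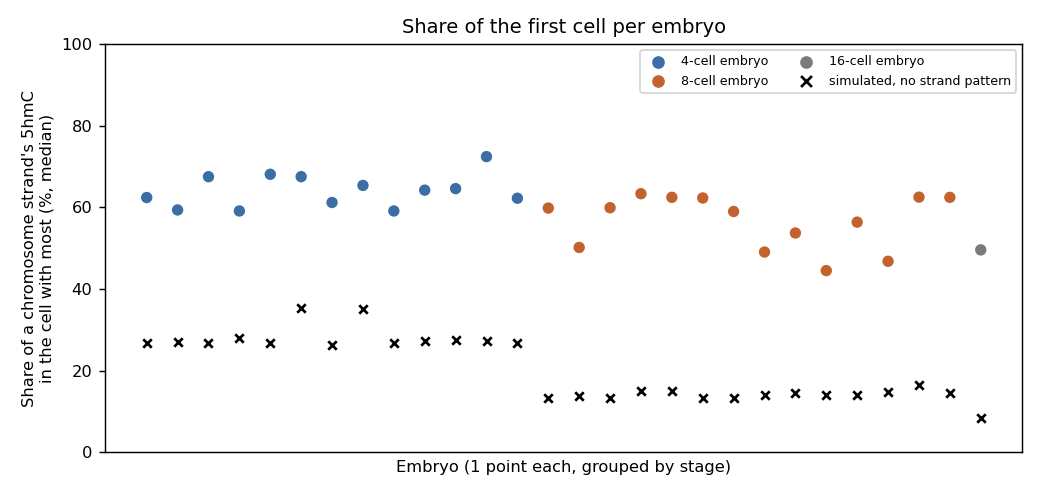
Share of the 5hmC of a chromosome strand in the cell of the embryo that holds most (percent, median over autosomes and both strands), for each of 28 embryos (points, coloured by stage). Crosses are the same detections spread over chromosome strands by the shares of the whole embryo. Each cell was first scaled to its own total over the autosomes. The 4-cell embryos lie between 59.1% and 72.4% and the 8-cell embryos between 44.5% and 63.3%, each above its own cross.

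In mouse plates, introns carried the most 5hmC per CpG of the annotated classes, and promoters and CpG-dense stretches the least. Relative to their share of CpGs, introns stood at 1.14 ± 0.003 in 4-cell libraries (SD, n = 3) and 1.17 ± 0.031 in 8-cell plates of run 2 (n = 5). Promoters stood at 0.291 ± 0.006 and 0.329 ± 0.025, and CpG-dense stretches at 0.146 ± 0.012 and 0.159 ± 0.014. Exons stood at 0.874 ± 0.013 and 0.953 ± 0.083. Intergenic CpGs stood at 1.00 ± 0.003 and 0.962 ± 0.036. For intergenic CpGs and promoters the exact permutation p was 0.0357, and over the 5 classes the lowest adjusted p was 0.0893, so none passed.

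No 1-Mb bin passed the threshold between 4-cell libraries and 8-cell plates of run 2. Of 2560 bins tested with limma-trend, 0 passed, 129 had an unadjusted p under 0.05, and the lowest adjusted p was 0.945. Voom weights, the other tool run, gave 0 as well, with 154 under 0.05 unadjusted. Among the 10 bins of lowest p that were higher in 4-cell libraries, 6 lay on chromosome 12. The first was chromosome 12 from 67000001 to 68000000 (mm10), which holds part of the neuronal adhesion gene Mdga2, with 333 ± 42 CPM, the detections scaled to the total of a plate, against 164 ± 53 (n = 3 and 5, log2 fold change 1.04 ± 0.29 SE, adjusted p = 0.945). Chromosome 15 from 19000001 to 20000000, with the cadherin gene Cdh10, had 314 ± 56 against 157 ± 64. Among the 10 in the other direction, chromosome 4 from 133000001 to 134000000, with 24 protein-coding genes including Arid1a, a subunit of a chromatin remodelling complex, had 416 ± 76 against 657 ± 98 (log2 fold change -0.66 ± 0.19 SE, adjusted p = 0.945). Chromosome 6 from 53000001 to 54000000, with Creb5, had 370 ± 111 against 571 ± 123. The median log2 fold change of bins was 0.17 on chromosome 12 (117 bins), 0.16 on chromosomes 18 and 16 (88 and 95 bins) and -0.14 on X (156 bins), against 0.03 over all bins. The X value is no measure of stage, since the X share of a plate depends on which embryos it holds and ran from 1.73% to 4.40% within the 8-cell plates of run 2. Bins whose plates did not overlap made up 4.61%, where chance gives 3.57%.

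No gene body passed either. Of 3917 tested with limma-trend, 0 passed and 167 had an unadjusted p under 0.05, with a lowest adjusted p of 0.168. Voom weights gave 1 gene, Gm10800 (adjusted p = 0.0249). The 10 genes of lowest p with more 5hmC in 4-cell libraries included Nrxn3, a presynaptic adhesion gene on chromosome 12 from 88722876 to 90334935, with 747 ± 41 CPM against 488 ± 100 (log2 fold change 0.63 ± 0.20 SE, adjusted p = 0.751). Pcdh7, a protocadherin gene on chromosome 5 from 57717967 to 58133230, had 194 ± 10 against 98.0 ± 54.2. Kif16b, a kinesin gene, had 194 ± 40 against 93.7 ± 18.3, and Cntnap4, a neurexin-family gene, 211 ± 26 against 110 ± 23. The others were Stxbp5l, Elp4, Galnt9, Phactr3, Helz and Epha6, with log2 fold changes from 0.73 in Epha6 to 1.55 in Stxbp5l and adjusted p from 0.801 to 0.892.

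Among the 10 genes of lowest p with less 5hmC in 4-cell libraries, Gm10800, a predicted gene of 0.755 kb on chromosome 2 from 98666547 to 98667301, had 2529 ± 592 CPM against 3827 ± 698 (log2 fold change -0.61 ± 0.13 SE, adjusted p = 0.168). Its level is uncertain, since 2814 detections over 0.755 kb can include reads of near-identical copies elsewhere. Zc3h7a, a zinc finger gene on chromosome 16 from 11136592 to 11176393, had 13.9 ± 12.6 against 87.9 ± 59.6 from 43 detections (log2 fold change -2.68 ± 0.66 SE, adjusted p = 0.276). Gm10800 and Zc3h7a both passed with no filter on low sums (adjusted p = 0.00154 and 0.00845) and with a pseudocount of 2 (adjusted p = 0.00333 and 0.0256). In these settings the median log2 fold change over all genes tested was -0.21 and -0.11, against -0.005 in the main setting. In both settings the median gene thus lay lower in 4-cell libraries, the direction of these calls. The log2 fold changes of Gm10800 and Zc3h7a did not grow with it. They were unchanged with no filter, and -0.61 and -1.91 with a pseudocount of 2. Why the 2 genes passed there was not tested. Gm10800 also passed without 8-cell plate 4 (adjusted p = 0.0436). Creb5, a transcription factor gene on chromosome 6 from 53287270 to 53700376, had 156 ± 80 against 309 ± 37 (log2 fold change -1.09 ± 0.28 SE, adjusted p = 0.276). Fam129a, Tex2 and Auh had the same adjusted p, with log2 fold changes of -1.64, -1.43 and -1.50. Deptor, an inhibitor of mTOR, Pknox1, Il34 and Actn4 had an adjusted p of 0.751 each.

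Of the 10 gene lists, 6 had at least 3 measured members, and 1 passed, the long neuronal genes. Members are counted as higher or lower by the fitted log2 fold change, the difference of mean logs. Of the long neuronal genes, 25 of 40 had higher and 15 lower values in 4-cell libraries, with a median log2 fold change of 0.06 (camera with Benjamini-Hochberg adjustment over 6 lists, adjusted p = 0.0407). With an estimated correlation the list did not pass (adjusted p = 0.496), nor with fry (adjusted p = 0.855), and 0 of its members passed, over all genes or adjusted over the list alone. The call was also lost without 4-cell library 1 or 2 or without 8-cell plate 6, 8 or 9. Its members with most detections were Rbfox1, a splicing regulator, with 973 ± 111 CPM against 780 ± 77, Macrod2 with 869 ± 130 against 763 ± 114, and Cdh13, a cadherin gene, with 851 ± 79 against 760 ± 234.

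The other 5 lists did not pass by camera, and 0 of their members passed over all genes or adjusted over the list alone. Of the imprinted genes, 8 of 13 were higher and 5 lower in 4-cell libraries (adjusted p = 0.219). Trappc9 had 347 ± 36 CPM against 335 ± 55, Kcnq1 134 ± 32 against 108 ± 66 and Sfmbt2 127 ± 36 against 109 ± 83. Of 4 genes of the DNA methylation machinery, 2 were higher and 2 lower. Tet3, the oxidase of the zygote, had 63.2 ± 14.7 against 74.2 ± 27.2, Tet2 70.7 ± 28.2 against 61.4 ± 34.9 and Dnmt3a, a de novo methyltransferase, 61.1 ± 20.9 against 55.3 ± 15. Of 6 primitive endoderm genes 2 were higher and 4 lower, with Lama1 at 121 ± 35 against 92.6 ± 39.3, Cubn at 89.4 ± 29.5 against 103 ± 20 and Dab2 at 94.6 ± 47.2 against 72.2 ± 16.6. Trophectoderm genes numbered 3, of which 1 was higher. Fgfr2, annotated over 2961 kb, had 1483 ± 138 against 1597 ± 177, Wwtr1 38.9 ± 5.2 against 45 ± 28.7 and Tead4 37.9 ± 18.8 against 27.8 ± 26.3. Human FGFR2 is annotated over 120 kb, so the mouse span can take in other genes, and its value is no clear measure of Fgfr2. Of 3 genes of cumulus and granulosa cells, the cells that surround the oocyte, 2 were higher and 1 lower, with Fshr at 77.3 ± 12.7 against 93.3 ± 44.6, Kitl at 46.6 ± 20.0 against 39.2 ± 19 and Cyp19a1 at 40.8 ± 6.7 against 45.1 ± 42.6. Cyp19a1 counts as higher by its log2 fold change of 0.19 ± 0.59 SE although its mean CPM is lower, so its direction is not settled. These 4 lists had an adjusted p of 0.942 each. The median and the mean log2 fold change of the trophectoderm list differed in sign, at -0.07 and 0.18.

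The 4 remaining lists had too few measured members for a set test. Among 21 pluripotency genes only Esrrb was measured, with 63.0 ± 17.7 CPM against 74.0 ± 35.8. The only measured gene of zygotic genome activation was Nr5a2, with 47.1 ± 26.8 against 112 ± 40 (log2 fold change -1.28 ± 0.40 SE, adjusted p = 0.751). Hox genes held 44 detections over 39 genes and housekeeping genes 85 over 15, so neither list was measurable at this depth. Sall4, Tfcp2l1, Sdha, Rplp0, Hprt, Arg2, Dppa2, Hoxc5, Hoxb3 and Hoxd11, named by the rule for these lists, had 3 to 21 detections each.

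The 8-cell plates of the 2 runs, named HybEmb in run 1 and NonHybEmb in run 2 by the authors, differed most in the number of sites. Run 1 held 24085 ± 4316 sites per cell (SD, n = 3) and run 2 3926 ± 1172 (n = 5), a log2 difference of 2.65 (exact permutation p = 0.0357, adjusted p = 0.107 over 3 measures). Strand asymmetry was 0.457 ± 0.047 and 0.483 ± 0.061, a difference of -0.026 (exact permutation p = 0.607, adjusted p = 0.607). Persistence was 0.872 ± 0.024 and 0.784 ± 0.046, a difference of 0.088 (exact permutation p = 0.0714, adjusted p = 0.107). Promoters stood at 0.207 ± 0.011 of their share of CpGs in run 1 and exons at 1.06 ± 0.005, next to the 0.329 ± 0.025 and 0.953 ± 0.083 of run 2, without a test. The plate with 8- and 16-cell embryos, plate 7, had a median of 2660 sites per cell over 23 cells, an asymmetry of 0.546 and a persistence of 0.813.

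In H9 cells, 5hmC was less uneven over the strands than in any mouse plate, and genomic DNA was even. Strand asymmetry averaged 0.133 with BseRI (52 cells), 0.0892 with BseRI and AluI (33 cells), 0.105 with AluI (30 cells) and 0.125 with AbaSI alone (58 cells). BseRI detections of genomic DNA, the background for strands, gave -0.00018 in 51 cells and 0.0000644 in 31 cells. The same-strand excess of 5hmC persisted along the chromosome, with 0.907 to 0.958 of its short-range value left at 50 to 100 Mb. Each H9 library is single, so these values have no replicate check. Adding a digestion of genomic DNA went with medians of 19244 sites per cell with BseRI, 8389 with both enzymes and 7506 with AluI, against 21058 with AbaSI alone. Over 1-Mb bins the 5hmC profiles of the 4 libraries, on a log2 scale, correlated with a mean Pearson r of 0.973 over 6 pairs. On the same scale 5hmC correlated with BseRI detections at 0.892 and with AluI detections at 0.853 on average. Bins are not independent replicates. Relative to their share of CpGs, exons stood above introns with AbaSI alone (1.18 against 1.09) and with BseRI (1.11 against 1.09) and below them with BseRI and AluI (0.999 against 1.09) and with AluI (0.972 against 1.08). Promoters stood from 0.581 to 0.694 and CpG-dense stretches from 0.453 to 0.630.

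The H9 genes of highest 5hmC density in the AbaSI-only library were FIBCD1, a membrane receptor gene on chromosome 9 from 133777825 to 133814673 (hg19), and CA4, a carbonic anhydrase gene on chromosome 17 from 58227303 to 58248260. FIBCD1 had 4.97 CPM per kb (95% interval 4.36 to 5.64, 241 detections) and CA4 4.93 (4.14 to 5.83, 136 detections), where the median gene of at least 20 kb had 0.290. ABCA7, a lipid transporter gene, MLLT6, PWWP2B, CRB2, BCL9L, a Wnt pathway cofactor gene, EPHB3, an ephrin receptor gene, DOK7, PLXND1, CHRNA4, SMAD7, an inhibitor of TGF-β signalling, CASZ1, TSPAN4 and CXXC5 followed, with 4.60 in ABCA7 to 4.03 in CXXC5. These levels were lower in the other 3 libraries, for FIBCD1 1.84 to 3.48 and for SMAD7 2.25 to 3.63. They also follow the number of CpGs. Density correlated with CpGs per kb at r = 0.724 over genes, and 4 of the 15 stayed among the highest 15 per CpG, where CA4 was first with 245 detections per 1000 CpGs, scaled as CPM. Relative to BseRI detections of the same gene 2 of the 15 stayed, and relative to AluI detections 7.

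**Figure D4:**
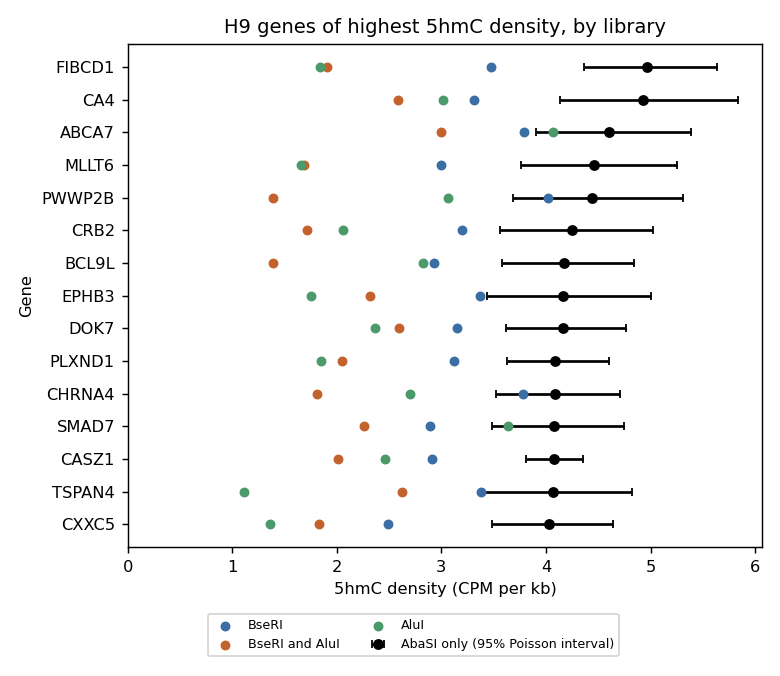
5hmC density in CPM per kb in the 15 H9 genes of highest density in the AbaSI-only library (black, with exact 95% Poisson intervals) and in the other libraries (coloured points), on a linear axis from 0. For 15 of 15 genes the AbaSI-only value is the highest of the 4, the library in which the genes were chosen.

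Of 11628 H9 genes of at least 20 kb, 167 had no detection in the AbaSI-only library. C6, a complement gene of 119 kb on chromosome 5, had 0 detections, which allows up to 0.0191 CPM per kb, but 0.0820 to 0.114 in the other libraries, and 67 BseRI detections of genomic DNA in the BseRI library. OR4N2, an olfactory receptor gene, and ANKRD30A had 0 as well, with 88 and 46 BseRI detections. GABBR1 had 0 detections of 5hmC in each library and also 0 of genomic DNA in the BseRI and AluI libraries, so nothing can be said of its 5hmC. NXF2, NXF2B and an unnamed gene that overlaps NXF2B had 0 detections of 5hmC with AbaSI alone and 5 to 15 BseRI detections.

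Hox genes, the patterning genes of the body axis, had dense 5hmC detections in H9, by length and, less so, by CpG. List values were not set relative to genomic DNA detections, so uneven coverage of genes is not taken off. All 39 lay above the median of all genes, 0.357 CPM per kb, with a median of 1.87. They lie in 4 clusters and some overlap, so members share detections, and random lists were drawn with the same clustering. Of 10000 such lists 53 reached that median (percentile 99.5). Per 1000 CpGs, a scale added after the data had been seen, as were the clustered draws, their median was 49.1 against 26.6 over all genes, and 204 lists reached it (percentile 98.0). HOXB3 had 1.86 CPM per kb, HOXA3 2.06 and HOXC6 1.49. Genomic DNA was dense there too, with 1.44, 0.887 and 1.27 CPM per kb of BseRI detections in the BseRI library. How much of the Hox density goes with coverage was not tested. Imprinted genes (31 measured) were at the 97.8th percentile per kb with a median of 0.596 and at the 93.7th per CpG, with TRAPPC9 at 1.04, KCNQ1 at 1.39 and GRB10 at 0.680 CPM per kb. Trophectoderm genes (18) were at the 97.7th per kb and the 87.8th per CpG, with FGFR2 at 1.28, TEAD4 at 1.42 and WWTR1 at 0.478. Primitive endoderm genes (13) were at the 97.6th and the 91.6th, with COL4A2 at 0.996, COL4A1 at 0.946 and GATA4 at 1.29.

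Long neuronal genes (39) were at the 8.99th percentile per kb, with a median of 0.188, and at the 20.6th per CpG, where their median of 26.2 per 1000 CpGs lay near the 26.6 of all genes. RBFOX1 had 0.518 CPM per kb, NTM 0.774 and OPCML 0.549. Pluripotency genes (20) were at the 73.1st percentile per kb but the 33.6th per CpG, with ESRRB at 1.18, TFCP2L1 at 0.432 and NODAL at 1.80. The DNA methylation machinery (18) was at the 67.5th per kb and the 33.0th per CpG, with DNMT3A at 3.01, TET3 at 1.04 and DNMT3B at 1.44. Zygotic genome activation genes (3) were at the 55.1st and 42.5th, with NR5A2 at 0.375, DPPA2 at 0.368 and ARG2 at 0.143. Housekeeping genes (13) were at the 47.5th and 32.9th, with ACTB at 1.24, GAPDH at 4.72 and PGK1 at 0.0800. Cumulus and granulosa genes (12) were at the 39.7th and 56.9th, with NR5A1 at 3.77, CYP19A1 at 0.291 and FSHR at 0.0987. The percentiles describe this library and are no test between conditions.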

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

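In groups of 4 to 10 samples, the highest or lowest sample was compared with its neighbours. Of 62 groups tested, 4 had a sample far from the others, and chance gives about 1 in 20 groups. The embryo measures were chosen after the data had been seen.

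Among 7 embryos at the 8-cell stage of run 1, embryo 2 of 8-cell plate 1 had the lowest share in its first cell, 50.2%, with the nearest other embryo at 59.0%. The same embryo had the highest effective number of cells per chromosome strand, the inverse of the sum of squared shares, 2.92, with the nearest at 2.43, a second view of the same shares. Well 17 of this embryo had only 1365 detections and a strand asymmetry of 0.027, and was scaled to its own total like the other cells. Well 1 of embryo 1 on that plate had 1826 and 0.071, and the first cell of embryo 1 held 59.8%. In 8-cell plates of run 2, Elp4, a gene of the Elongator complex, had 128 CPM in plate 9, with the nearest plate at 44.6. Il34, a cytokine gene, had 167 CPM in plate 8, with the nearest at 69.9. No explanation was tested for these values. The genes have 72 and 46 detections over the 8 plates, and neither passed between the stages.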

How the results depend on the processing

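The settings named here as added were chosen after the data had been seen: cells of the authors' list, embryos as replicates, voom, a pseudocount of 2, median-of-ratios scaling of bins and genes, autosomes only, fry, density per CpG, rankings in other H9 libraries and the joint drawing of neighbouring members of H9 gene lists. Here single measures are judged by their unadjusted p, and regions and lists by the adjusted p. Of all values recomputed for the main results, 135 stayed on their side of 0.05 or within their spread, 17 ended above it, 7 came below it and 11 moved by more than their spread. None turned direction where the main or the recomputed p was below 0.05. A turn between values that were both above 0.05 counts as stayed. Of the 17, 8 are the sites per cell without 1 plate, where the design cannot reach 0.05. For named genes and bins 1059 stayed and 6 came past the threshold, namely those of Gm10800 and Zc3h7a. The count model tests planned for bins and genes, a DESeq2 Wald test and edgeR with and without TMM, were not run: they were kept for counts as deposited, and the deposited columns hold positions. The sums per region made here are whole numbers, so a count model could be fitted to them, and what it would call is not known. No paired analysis was possible because the 4-cell libraries and the 8-cell plates of run 2 share no replicate number.

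The log2 difference in sites per cell was 0.074 with both runs (exact permutation p = 0.921, 3 against 8), since run 1 holds more sites, and 1.02 with listed cells (exact permutation p = 0.0714; the cause was not tested). Leaving out 1 plate gave 0.82 to 1.24, where the smallest exact p is 0.0952 or 0.0571, so nothing follows on stability. The difference in asymmetry was -0.152 with 30 detections per chromosome and -0.204 with thinned cells, and the cause was not tested. That in persistence was -0.099 with both runs, since run 1 has a higher persistence. Leaving out 1 plate gave -0.078 to -0.028 for asymmetry and -0.083 to -0.042 for persistence, each smallest without 4-cell library 2. The complementary pattern stayed under all its alternatives, from -0.120 to -0.102 without 1 plate. The bins stayed at 0 in each setting. The count of genes was 2 with no filter, 1 with voom and 2 with a pseudocount of 2, and 0 to 1 when 1 plate was left out (1 without 8-cell plate 4); the cause was not tested. The count of lists was 0 with an estimated correlation, 0 with fry, and 0 to 1 when 1 plate was left out.

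In H9 the mean correlation of bins on a log2 scale was 0.986 between 5hmC profiles, 0.946 with BseRI and 0.880 with AluI in 5-Mb bins. In 1-Mb bins it was 0.726, 0.747 and 0.691 with thinned cells, which have fewer detections. Of the 15 densest genes, 2 stayed relative to BseRI, 7 relative to AluI, 4 per CpG, 5 when ranked with BseRI and AluI and 6 with AluI, but 10 when ranked with BseRI and 11 among genes of at least 5 kb. With random H9 lists of scattered genes, which ignore that members lie side by side, the Hox genes stood at percentile 100 per kb and 99.97 per CpG, against 99.5 and 98.0 with clustered lists, and imprinted genes at 99.3 and 96.3 against 97.8 and 93.7. The median sums over the 8 plates were 346 per bin and 53 per gene, and simulated 2-fold changes were called for 79.0% of 100 bins and 24.7% of 77 genes.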

Other observations

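Tests by embryo were chosen after the data had been seen, as were the simulation of few detections, the comparison of X shares between embryos on either side of the gap in Y detections with their ratio, the correlations of X with Y within the 13 and the 15 embryos, the drawing of different first cells, and both tests of the H9 spread that use the ratio of coefficients of variation. The other tests below were planned.

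In mouse embryos, the share of 5hmC detections on the X chromosome fell into separate ranges. Of 28 embryos, 13 had 2.57 to 8.68 Y detections per 10000 and a median X share of 4.20% (3.36% to 5.56%), and 15 had 11.1 to 33.0 and a median of 1.21% (0.584% to 2.03%). These are embryos parted by the data and are not groups of the study.

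The X share of all 13 embryos with few Y detections lay above that of each of the 15 with many, as the number of X chromosomes would require. This replaced a planned rank correlation over all embryos, which had the predicted sign but is not given because the embryos form 2 clusters. Within the 13 embryos Pearson's r was 0.356 (permutation p = 0.233) and Spearman's rho 0.390 (p = 0.190), and within the 15 they were 0.195 (p = 0.489) and 0.264 (p = 0.340); without the 2 embryos farthest on Y, r was 0.277 and 0.221. With 2 X chromosomes against 1 and equal 5hmC on each, the ratio would lie near 2, whereas that of medians was 3.46 (95% bootstrap interval 3.06 to 4.36), with 3.25 in run 1 (1.95 to 6.76, 2 embryos against 5) and 3.65 in run 2 (2.97 to 4.62, 11 against 10). What raises the ratio stays open, parental origin of the X included, which was not tested, and run 1 has too few embryos to bear on it alone.

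The concentration of a chromosome strand's 5hmC in few cells was set against technical sources. Uneven recovery of whole chromosomes would make the same cell first for both strands, but this happened 18.3 percentage points less often than an even draw (-18.3, below it in 28 of 28 embryos, sign-flip permutation p = 1e-05, the smallest the draws can give). In 28 of 28 embryos the first cell's share lay above the highest of 100 simulations in which neither strands nor chromosomes differed between cells. Few detections thus do not account for it. In the 11 of 13 embryos at the 4-cell stage with all 4 cells past the minimum, the best way to form pairs put the first cells of plus and minus strands in different pairs for 94.3% ± 6.0 of autosomes (SD), against 61.3% with shuffled strands (highest 70.3%, permutation p = 0.001, the smallest 1000 shuffles can give). Since that shuffle lets the same cell come first for both strands, the first cells were also drawn as different cells, which gave 77.1% (highest of 1000 draws 83.3%, permutation p = 0.001, again the smallest), so the excess over different cells alone may reflect old strands passed on whole to different cell pairs of the embryo, a hypothesis found and tested on the same data.

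5hmC per autosome varied between H9 cells more than genomic DNA did. With counting variance taken off, the coefficient of variation was 14% to 19.1% for 5hmC and 4.15% to 6.21% for genomic DNA of the same cells, a ratio of at least 2.53, which argues against fewer detections of 5hmC as its source. Genomic DNA varied by at most 39.5% of the spread of 5hmC, which argues against gains and losses of chromosomes as the whole of it. A part stays open: the median correlation of both per cell over autosomes was 0.269 in the BseRI library, between the bounds of 0.3 and 0.1 set for this test, and below 0.1 in the others, at -0.0504 and 0.0996 for BseRI and AluI in the library with both and -0.0270 in the AluI library. No biological explanation was tested.

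The 8 plates were also split into 3 and 5 in each other way. For bins and gene bodies the real count was 0, which each of the 56 splits (56 of 56) meets by construction, so nothing follows on chance; the highest of the other splits was 4 bins and 1 gene body. For gene lists, 15 of 56 splits gave as many as the real 1, with 1 as the highest of the others, so chance is not excluded.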
